A study of Homo sapiens with 14 samples.

How the data were processed

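Chromatin immunoprecipitation and sequencing was done in K562 cells with antibodies against HSF1 and HSF2 and with non-specific IgG, in cycling and mitotic cells with and without heat. The labels give 14 samples in 14 groups, so each group holds 1 library, and each library was made from 10 pooled immunoprecipitations per the labels' protocols. The 12 antibody libraries each have a peak list. The 2 input libraries, 1 per cell state and labelled as heat-treated, have none and entered as the control of the lists.

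Per the submitters' processing notes, reads were aligned with Bowtie to hg19 and peaks were called with MACS 1.4. Per the file headers, the program was MACS 1.4.1 with a p cutoff of 1e-05, an effective genome size of 2700000000 bp, a fragment size (d) of 200 bp and a cap on duplicate tags of 2 or 1 per position. Per the file headers, the alignment names carry bwa in 5 lists of cycling cells, which differs from the notes, and another naming in the other 7 lists (all 6 mitotic lists and non-treated cycling IgG). The naming therefore goes almost with cell state. The 1 list with accession names for chromosomes, non-treated cycling IgG, was renamed to 1 to 22, X and Y.

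The tags column holds counts of tags in the peak, per the file headers. The score is deposited as minus 10 times log10 of the MACS p-value. The fold is a ratio of ChIP to expected input tags at the summit, as deposited. The FDR is a percent, as deposited. Total and kept tags per library were read from the headers, and kept tags ranged from 2066373 to 28676943. Input libraries had 34815679 kept tags for cycling cells (36542527 in the control of non-treated cycling IgG) and 38337720 for mitotic cells.

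From the lists, target sites were taken as deposited peaks with a fold of at least 10 that did not overlap by 1 bp an IgG peak of the same cell state and treatment with a fold of at least 10. Overlap of at least 1 bp counted as shared. Shares have 95% Wilson intervals, a count of 0 has the limit that 3 counts give, and tags in a peak scaled to 1000000 kept tags (CPM) have exact Poisson intervals. All of these cover counting error only. Overlap by chance was described with 1000 random placements on the same chromosomes. The main definition, the comparisons and the rule for named sites were set before the data were examined. The McNemar tests on sites (10 in 1 family, Benjamini-Hochberg adjusted, two-sided and exact), the 4 groups by fold, the chromosome counts (48 in 1 family for each kind of test) and the depth-scaled fold were chosen after the data were seen. The depth-scaled fold is the deposited fold times the input kept tags over the ChIP kept tags.

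Named sites are the 10 sites of highest fold in each HSF list, or all where a list has fewer, and the sites with a peak in all 8 HSF lists. Sites outside this rule are said to be chosen after their values were seen. Alternatives covered the fold minimum (none, 5, 15 and 20), a score of 100 in place of the fold, an FDR of at most 5%, 4 ways of treating IgG peaks, 50% reciprocal overlap, summits within 250 bp, all deposited peaks as partner and lists of equal length. Added after the data were seen were a depth-scaled fold of at least 20, the leaving out of sites with a heat-treated mitotic IgG peak, and the alternatives named above for the shares of heat-treated cycling sites with a peak in another list.

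The steps were tested on simulated data. In a simulated list with 100 planted sites among 285, for mitotic against cycling HSF1 with heat, overlap, summit distance and reciprocal overlap each recovered 100. The planted sites were exact copies, so this checks the code and not shifted summits or unlike widths. Counts of overlap were compared with bedtools in 144 pairs of lists and differed in 0. Random placements gave a mean of 1.13 overlaps where 1.27 were expected from the covered length, over 285 sites. Over 1500 simulated regions, the slope of fold per tag on depth came out at 0 for folds not corrected for depth and at -1 for corrected folds. The simulation fixes these slopes, so they too check the code alone. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.

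Heat shock elements, promoter sites and the fixed gene lists were not analysed here, because no genome or annotation of hg19 was at hand. The gene table at hand is of GRCh38 and was not used here, and sites are therefore given by position alone.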

Results

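Binding of heat shock factors HSF1 and HSF2 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in K562 cells, a human erythroleukemia line. HSF1 is the main activator of heat shock genes, and HSF2 is a related factor that recognises the same DNA element. Cells were either unsynchronised (cycling) or arrested in mitosis, and either kept at 37 °C (non-treated) or exposed to 42 °C for 30 min (heat-treated). Each of the 4 conditions has 1 HSF1, 1 HSF2 and 1 non-specific antibody (IgG) library. Each cell state also has 1 input library. The 14 samples therefore give 1 library per group, each from 10 pooled immunoprecipitations, without replicates. No test of a condition is possible, and the tests below compare lists of sites in these particular libraries. Peak lists exist for the 12 antibody libraries and hold 117699 peaks in total. Kept tags ranged from 2066373 in non-treated mitotic IgG to 28676943 in non-treated cycling HSF2. Intervals are 95% intervals that cover counting error only (Wilson for shares, exact Poisson for tags in a peak scaled to 1000000 kept tags, CPM). Coordinates are hg19.

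A target site is a peak with a fold enrichment over input of at least 10 that does not overlap an IgG peak of the same cells with a fold of at least 10. This IgG step removed 2 peaks, both of HSF2 in heat-treated mitotic cells. In the other conditions no IgG peak reached that fold (highest 8.87 and 8.75 in cycling cells without and with heat, and 8.41 in non-treated mitotic cells), so target sites there are not free of IgG signal. In heat-treated cycling cells, HSF1 had 285 target sites and HSF2 had 156. In non-treated cycling cells the same definition gave 1 HSF1 site and 5 HSF2 sites. Mitotic cells had few sites: 6 for HSF1 and 8 for HSF2 after heat, and 0 and 4 without heat. The deposited lists behind these counts held 6447 HSF1 and 4315 HSF2 peaks in heat-treated cycling cells. They held 4718 and 875 peaks in non-treated cycling cells, 4982 and 8270 in heat-treated mitotic cells, and 4534 and 19866 in non-treated mitotic cells. The fold as deposited is not adjusted for library depth, and the HSF1 mitotic libraries are shallow (6164898 kept tags without heat and 7385467 with heat, against 14446547 and 16735990 in cycling cells). At a depth-scaled fold of at least 20, a definition chosen after the data were seen, heat-treated mitotic cells had 77 HSF1 sites and 2 HSF2 sites. The same definition gave 315 HSF1 and 115 HSF2 sites in heat-treated cycling cells. The order of cycling and mitotic cells turned under other definitions: by a score of at least 100, heat-treated HSF1 had 2476 mitotic and 2256 cycling sites, and with no minimum heat-treated HSF2 had 5272 and 3793. By score, non-treated mitotic cells also had more sites than heat-treated ones, 2832 against 2476 for HSF1 and 8440 against 308 for HSF2. The score was not tested against depth, so counts by score may not compare libraries of unlike depth. On chromosome 19 at 23253697 to 23254638, non-treated mitotic IgG (2066373 kept tags) had 6 tags, 2.90 CPM and a score of 682. Heat-treated mitotic HSF2 (28299989 kept tags) had 87 tags, 3.07 CPM and a score of 308 there.

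**Figure D1:**
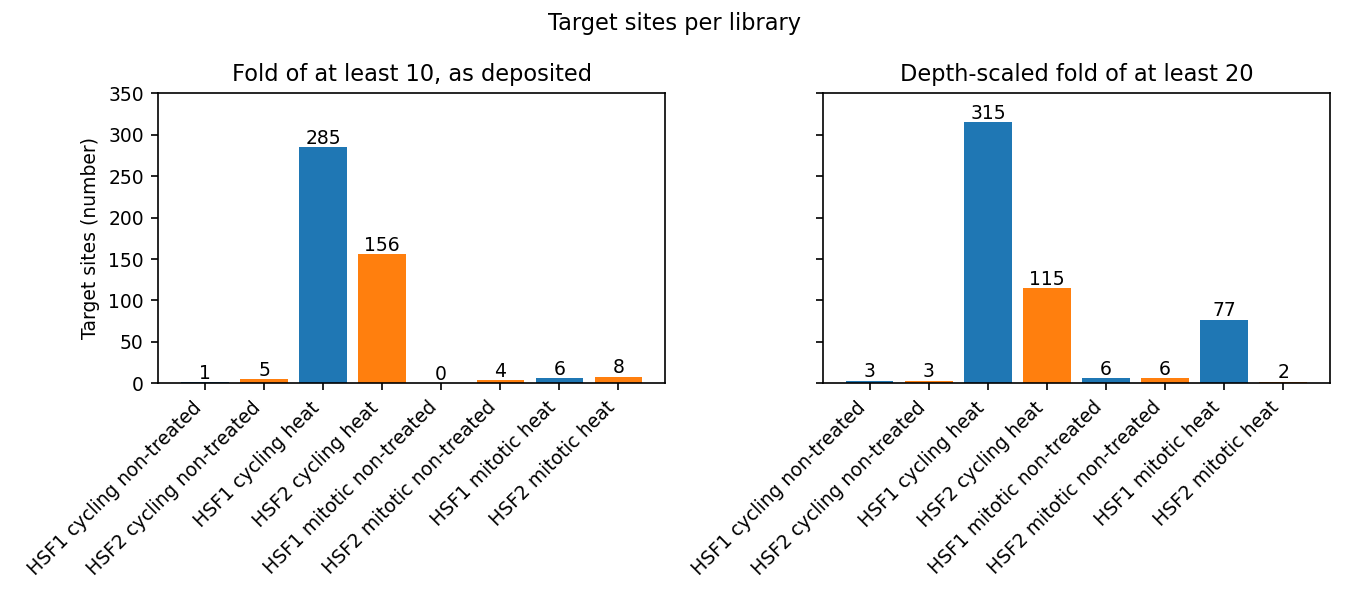
Number of target sites (vertical axis) in each of the 8 HSF libraries at a fold of at least 10 (one panel) and at a depth-scaled fold of at least 20 (other panel), 1 library per bar. Heat-treated cycling cells hold most sites under both definitions (285 and 156, or 315 and 115), while heat-treated mitotic HSF1 goes from 6 to 77.

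The comparison of heat-treated with non-treated cycling cells asks which loci gain the factors under heat stress. Most strong HSF1 peaks of heat-treated cells had no counterpart without heat. Of the 285 HSF1 sites, 16 (5.61%, 3.48 to 8.92) had any HSF1 peak in non-treated cells. Of the 156 HSF2 sites, 29 (18.6%, 13.3 to 25.4) had an HSF2 peak in non-treated cells. These shares depend on the fold minimum: at a fold of at least 20 they were 25% of 40 HSF1 sites and 61.1% of 18 HSF2 sites, and with no minimum 4.92% and 2.56%. On chromosome 16 at 89227208 to 89228470, the site with the highest HSF1 fold (46.3) held 202 HSF1 tags after heat (12.1 CPM, 10.5 to 13.9) and no peak in any non-treated or IgG list. The same region carried the highest HSF2 fold in heat-treated cycling cells (54.0, 231 tags, 11.9 CPM, 10.4 to 13.5). A pair of broad regions on chromosome 6 held the most HSF1 tags among the 10 HSF1 sites of highest fold. One, at 31794357 to 31797922, had 601 tags (35.9 CPM, 33.1 to 38.9), against 47 tags (3.25 CPM, 2.39 to 4.33) in a narrower peak of non-treated cells. The other, at 31782105 to 31785960, had 537 tags (32.1 CPM, 29.4 to 34.9), against 27 tags (1.87 CPM, 1.23 to 2.72).

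At 4 further sites of highest HSF1 fold no non-treated HSF list held a peak. A pair lay on chromosome 7, at 75923331 to 75924845 (fold 39.5, 284 tags) and at 27773783 to 27774970 (fold 38.9, 175 tags). The others were on chromosome 13 at 31735620 to 31736638 (fold 32.6, 109 tags) and on chromosome 12 at 655911 to 656943 (fold 30.2, 101 tags). On chromosome 12 at 125399635 to 125400639 (fold 30.7, 146 tags), a peak without heat was present in mitotic HSF2 alone. The chromosome 2 site at 198364229 to 198365255 (fold 43.0) carried 9.62 CPM of HSF1 after heat (8.19 to 11.2) and 1.38 without (0.846 to 2.14). On chromosome 6 at 160210392 to 160211604 (fold 31.8) the values were 9.44 (8.03 to 11.0) and 1.18 (0.686 to 1.88). Peaks were called separately in each library and differ in width, so these values describe each library's own peak. The fold is the authors' own value and serves to rank and filter sites within a list, and its depth-scaled form is compared between lists where said.

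Without heat, HSF2 occupied more of the later HSF1 sites than HSF1 did. HSF2 had a non-treated cycling peak at 34 of the 285 HSF1 sites (11.9%, 8.66 to 16.2) and HSF1 at 16. The difference passed an exact McNemar test over sites (24 sites in HSF2 alone, 6 in HSF1 alone, adjusted p = 0.00179 over 10 such tests, two-sided). IgG of non-treated cycling cells had a peak at 6 of the 285 sites, fewer than HSF1 (adjusted p = 0.0414, exact test). It had a peak at 7 of the 156 HSF2 sites, fewer than the 29 of HSF2 (adjusted p = 0.000162, exact test). These tests were chosen after the data were seen. Sites are not independent replicates, and the HSF2 library had 28676943 kept tags against 14446547 for HSF1.

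Among the 5 HSF2 sites of non-treated cycling cells, 3 were also HSF2 sites after heat. The deposited FDR of all 5 was 14.3% to 28.6%, so that an FDR of at most 5% leaves 0 of the 5. The strongest lay on chromosome 11 at 122932409 to 122933542 (fold 20.2, 77 tags, 2.69 CPM, 2.12 to 3.36). After heat the HSF2 peak there had 112 tags (5.75 CPM, 4.74 to 6.92) and the HSF1 peak 130 tags (7.77 CPM, 6.49 to 9.22). The chromosome 2 site at 198364246 to 198365320 had a fold of 17.8 (64 tags), and the chromosome 22 site at 41252279 to 41253240 a fold of 16.3 (63 tags). The remaining 2, on chromosome 1 at 14825195 to 14826476 (fold 16.6, 120 tags) and on chromosome 4 at 152950678 to 152951735 (fold 12.1, 66 tags), had no peak in any heat-treated list. Their other peak was in non-treated mitotic HSF2, with 15 and 27 tags. The single HSF1 site of non-treated cycling cells, on chromosome 11 at 19422958 to 19423794 (fold 11.1, 37 tags), recurred in heat-treated cycling IgG and in no other list.

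HSF1 and HSF2 shared nearly all strong sites in heat-treated cycling cells. HSF2 had a peak at 280 of the 285 HSF1 sites (98.2%, 96.0 to 99.2), and HSF1 had one at 155 of the 156 HSF2 sites (99.4%). As target sites of both factors, 132 HSF1 sites overlapped an HSF2 site. Summits lay close together, with a median distance of 19 bp over the 280 shared sites. IgG of the same cells, called against the same input, had a peak at 5 of the 285 sites (1.75%). Because HSF1 and HSF2 peaks of a cell state share an input, part of any overlap may come from it. That part was not measured, and the IgG count gives only the sites where IgG had a peak. Random placement of peaks on the same chromosomes gave a mean of 1.15 overlaps with the HSF2 list.

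The exceptions were few and were singled out after their values were seen. The 5 HSF1 sites without an HSF2 peak lay on chromosome 1 at 155214197 to 155215084, chromosome 11 at 20487382 to 20488258, chromosome 15 at 44580143 to 44581056, chromosome 16 at 28874476 to 28875354 and chromosome 19 at 42387872 to 42388787. The 1 HSF2 site without an HSF1 peak lay on chromosome 11 at 118306780 to 118307208 (fold 12.8, 37 tags). There, HSF2 was also found in mitotic cells with heat (fold 14.1, 52 tags) and without (fold 11.6, 44 tags). Heat-treated mitotic IgG had a weaker peak (fold 3.17, 13 tags), and no HSF1 list had one.

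The sites of highest HSF2 fold in heat-treated cycling cells were also HSF1 sites. On chromosome 19, one at 1354103 to 1355183 had an HSF2 fold of 33.7 (108 tags, 5.55 CPM) and an HSF1 peak of 95 tags (5.68 CPM). Another at 2679076 to 2680187 had an HSF2 fold of 29.7 (123 tags) and an HSF1 peak of 118 tags. On chromosome 16 at 89050052 to 89051594 the HSF2 peak had 144 tags (fold 24.6) and the HSF1 peak 173. On chromosome 11 at 286877 to 288376 they had 181 (fold 23.8) and 221 tags. HSF1 had a higher CPM than HSF2 at the chromosome 7 site at 75923336 to 75924846, with 17.0 (15.1 to 19.1) against 8.47 (7.23 to 9.87). This order was not particular to that site. Over 225 shared sites without a heat-treated mitotic IgG peak, the depth-scaled fold of HSF1 was higher at 213 and lower at 12. Those sites were selected in the HSF1 list, which favours HSF1.

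**Figure D2:**
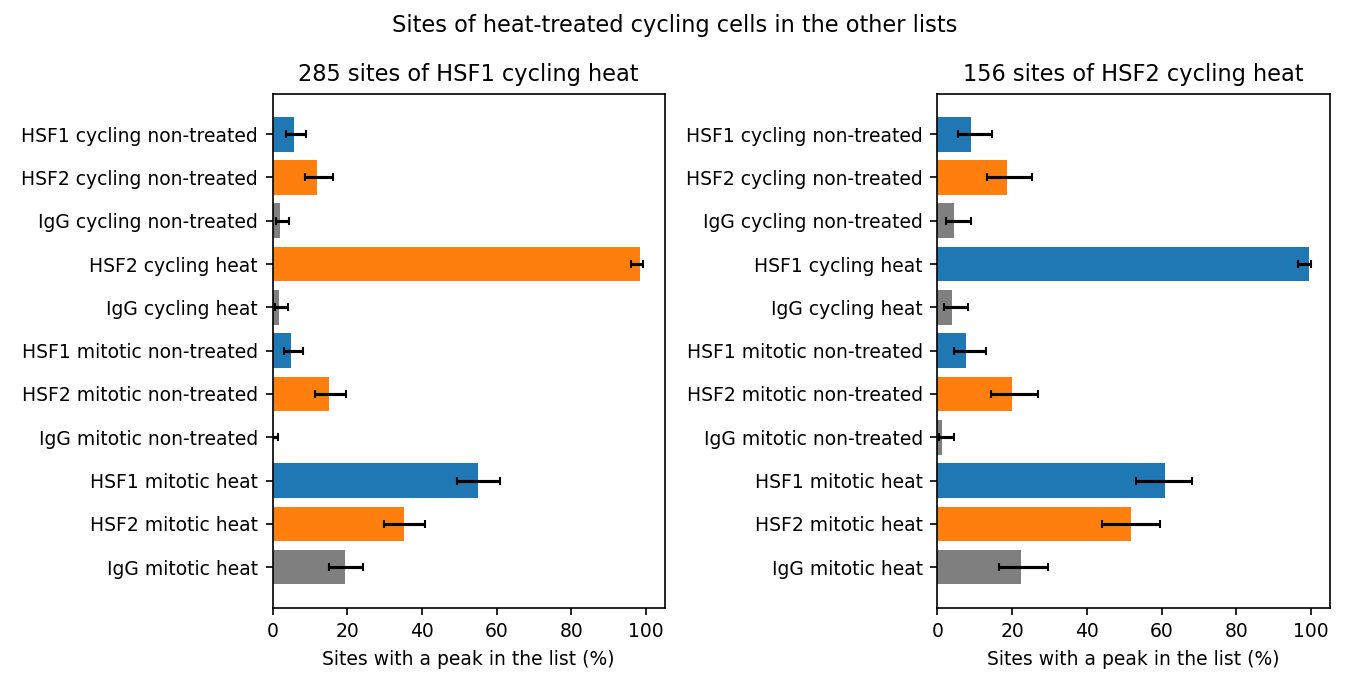
Percent of the 285 HSF1 and 156 HSF2 target sites of heat-treated cycling cells (horizontal axis) that have a peak in each other list (vertical axis), with 95% Wilson intervals as bars of counting error. The HSF1 sites have an HSF2 peak in 98.2% after heat, an HSF1 peak in 5.61% without heat, and a peak in heat-treated mitotic HSF1 in 55.1%, against 19.3% in heat-treated mitotic IgG.

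The comparison of mitotic with cycling cells asks which sites keep the factors when chromosomes are condensed. After heat, HSF1 had a mitotic peak at 157 of the 285 cycling sites (55.1%, 49.3 to 60.8), and without heat at 14 (4.91%). Any deposited mitotic peak counted here. Over the whole mitotic HSF1 lists, 29.9% of peaks with heat and 48.5% without had a fold below 1. HSF2 had a heat-treated mitotic peak at 81 of its 156 cycling sites (51.9%, 44.1 to 59.6), and a non-treated one at 31 (19.9%). Heat-treated mitotic IgG, the background measured in the same way, had a peak at 55 of the HSF1 sites (19.3%, 15.1 to 24.3) and at 35 of the HSF2 sites (22.4%). HSF1 exceeded IgG at its sites (adjusted p = 1.82e-20, exact McNemar test), and HSF2 exceeded IgG at its own (adjusted p = 1.38e-08). Mitotic HSF1 summits lay a median of 33 bp from the cycling summits, and IgG summits 275 bp. Without the sites where this IgG list has a peak, an alternative chosen after the data were seen, the HSF1 share was 50.4%. With no fold minimum for HSF and IgG peaks alike, which removes every peak that overlaps a matched IgG peak, the mitotic share was 10.4% for HSF1 and 10.3% for HSF2. At a fold of at least 20 it was 92.5% and 94.4%. Weaker cycling peaks showed no excess over heat-treated mitotic IgG by overlap. At folds of 5 to 10, 15.4% of 964 HSF1 peaks had a mitotic HSF1 peak and 15.7% a mitotic IgG peak. For HSF2 the shares were 15.3% and 17.3% of 753 peaks. Of the peaks found, 73.6% with HSF1 and 13.9% with IgG had summits within 100 bp, and 61.7% and 20% for HSF2 and IgG. These shares were not tested.

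The share of sites with a mitotic peak was highest among the strongest cycling sites. Sites were split into 4 groups of like size by fold. In the group of HSF1 sites with the highest fold, 58 of 72 (80.6%, 70.0 to 88.0) had a heat-treated mitotic HSF1 peak. The share was 45 of 71 in the next group, 31 of 71 in the one after, and 23 of 71 (32.4%, 22.7 to 43.9) in the lowest. For HSF2 the groups went from 31 of 39 (79.5%) through 24 and 19 to 7 of 39 (17.9%, 8.97 to 32.7). Heat-treated mitotic IgG was found at 17, 17, 11 and 10 sites of the HSF1 groups. No trend test was run over the groups. Weaker sites are more easily missed in peak calling, and this was not separated from a difference in binding. The heat-treated mitotic HSF1 library had 7385467 kept tags against 16735990 in cycling cells, while the mitotic HSF2 library was the deeper one.

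**Figure D3:**
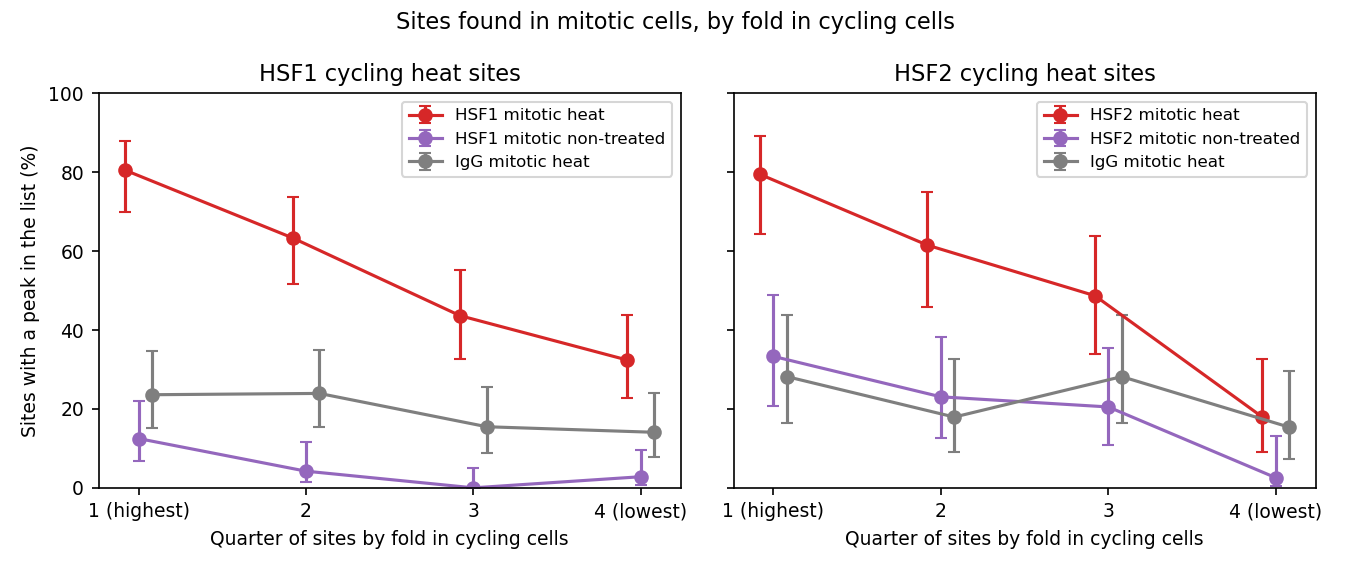
Percent of cycling heat sites (vertical axis) with a peak in heat-treated mitotic, non-treated mitotic and heat-treated mitotic IgG lists, in 4 groups by fold from highest to lowest (horizontal axis), with 95% Wilson intervals. The HSF1 share goes from 80.6% to 32.4% and the HSF2 share from 79.5% to 17.9%.

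All 6 HSF1 sites of heat-treated mitotic cells were HSF1 sites of heat-treated cycling cells. The chromosome 6 pair came highest by fold. The peak at 31794663 to 31796838 (fold 20.5) had 164 tags (22.2 CPM, 18.9 to 25.9), and the peak at 31782399 to 31784531 (fold 16.3) had 126 tags (17.1 CPM, 14.2 to 20.3). IgG peaks of the same cells at these places had 87 and 83 tags (4.84 and 4.62 CPM). On chromosome 2 at 198364221 to 198365408 (fold 15.1), 9.48 CPM of mitotic HSF1 (7.39 to 12.0) stood beside 9.62 in cycling cells. The site on chromosome 21 at 35444762 to 35445742 (fold 11.6) had 6.91 CPM in mitotic cells (5.14 to 9.08) and 3.59 (2.74 to 4.61) in cycling cells, and a mitotic IgG peak of 0.779 CPM (14 tags). The sites on chromosome 7 at 157128950 to 157129980 (fold 11.2) and 75923636 to 75924569 (fold 10.5) had 7.45 and 7.18 CPM. Heat-treated mitotic IgG had a peak at the former (1.28 CPM, 23 tags) and none at the latter, so that 4 of the 6 sites had such a peak and their removal leaves 2.

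Of the 8 HSF2 sites of heat-treated mitotic cells, 6 were HSF2 sites of heat-treated cycling cells. They included the chromosome 16 site at 89227304 to 89228441 (fold 13.7), the chromosome 11 site at 122932389 to 122933522 (fold 12.3) and the chromosome 19 site at 1354085 to 1354971 (fold 10.6). The chromosome 6 pair, at 31794729 to 31797893 (fold 15.5) and 31782609 to 31785476 (fold 10.8), and the chromosome 11 site at 118306567 to 118307317 (fold 14.1) were the others. The highest fold, on chromosome 1 at 221229070 to 221230129 (19, 75 tags, 2.65 CPM, 2.08 to 3.32), was at a region with no peak in any other list. The chromosome 19 site at 23253697 to 23254638 (fold 10.9) had a peak in all 12 lists, including IgG. IgG of the same cells had a peak at 5 of the 8 sites, and removal of these leaves 3.

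In heat-treated mitotic cells HSF1 was found at more of the cycling HSF1 sites (157) than HSF2 was (100), with 74 in HSF1 alone and 17 in HSF2 alone (adjusted p = 2.98e-09, exact McNemar test). At the 156 HSF2 sites HSF1 was found at 95 and HSF2 at 81 (adjusted p = 0.0320, exact test). The HSF1 library had 7385467 kept tags and the HSF2 library 28299989. The 2 lists may not be of like stringency. The deposited HSF1 peaks had a median of 11 tags and 29.9% had a fold below 1, against 21 tags and 0% for HSF2. Without heat, HSF2 was found at 43 of the 285 sites (15.1%) and HSF1 at 14 (adjusted p = 2.56e-05, exact test). That HSF2 list held 19866 peaks from 14782391 kept tags and the HSF1 list 4534 from 6164898, and summits lay within 100 bp of the cycling ones at 18 and 10 sites, a difference that was not tested. More sites had a mitotic peak in the heat-treated than in the non-treated library, 157 against 14 for HSF1 at its sites (adjusted p = 1.22e-39, exact test) and 81 against 31 for HSF2 at its own (adjusted p = 2.71e-12, exact test). Mitotic IgG also rose, from 0 to 55 at the HSF1 sites and from 2 to 35 at the HSF2 sites. The heat-treated libraries were deeper, with 28299989 against 14782391 kept tags for HSF2 and 17981369 against 2066373 for IgG.

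Non-treated mitotic cells had 4 HSF2 sites and no HSF1 site. The strongest HSF2 site, on chromosome 17 at 31148864 to 31150300 (fold 16.9, 344 tags), had a heat-treated mitotic IgG peak of higher fold (23.6, 457 tags). The chromosome 1 site at 156185714 to 156187213 (fold 10.7, 763 tags) and the chromosome 7 site at 155142452 to 155143633 (fold 10.1, 60 tags) likewise had strong IgG peaks of heat-treated mitotic cells (folds 13.8 and 10.3). IgG of the same cells also had a peak at these 3 sites, with 16.9 CPM against 23.3 for HSF2 on chromosome 17, 41.6 against 51.6 on chromosome 1 and 3.39 against 4.06 on chromosome 7, and removal of these leaves 1 of the 4. The fourth site was the chromosome 11 region at 118306553 to 118307395 (fold 11.6). All 5 HSF2 sites of non-treated cycling cells had a peak in the non-treated mitotic HSF2 list.

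Of the 316 merged regions that hold a target site in any library, 9 had a peak in all 8 HSF lists. At 2 of them, on chromosome 2 at 198364221 to 198365512 and on chromosome 11 at 122932364 to 122933595, no IgG list had a peak. The chromosome 6 pair and the chromosome 11 region starting at 286877 also had peaks in every HSF list, with peaks in 2 and 1 of the IgG lists. At 4 of the 9, all 4 IgG lists had a peak as well. These 4 were on chromosome 1 starting at 156185714, chromosome 17 starting at 31148864, chromosome 19 starting at 23253697 and chromosome 20 starting at 26188506.

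**Figure D4:**
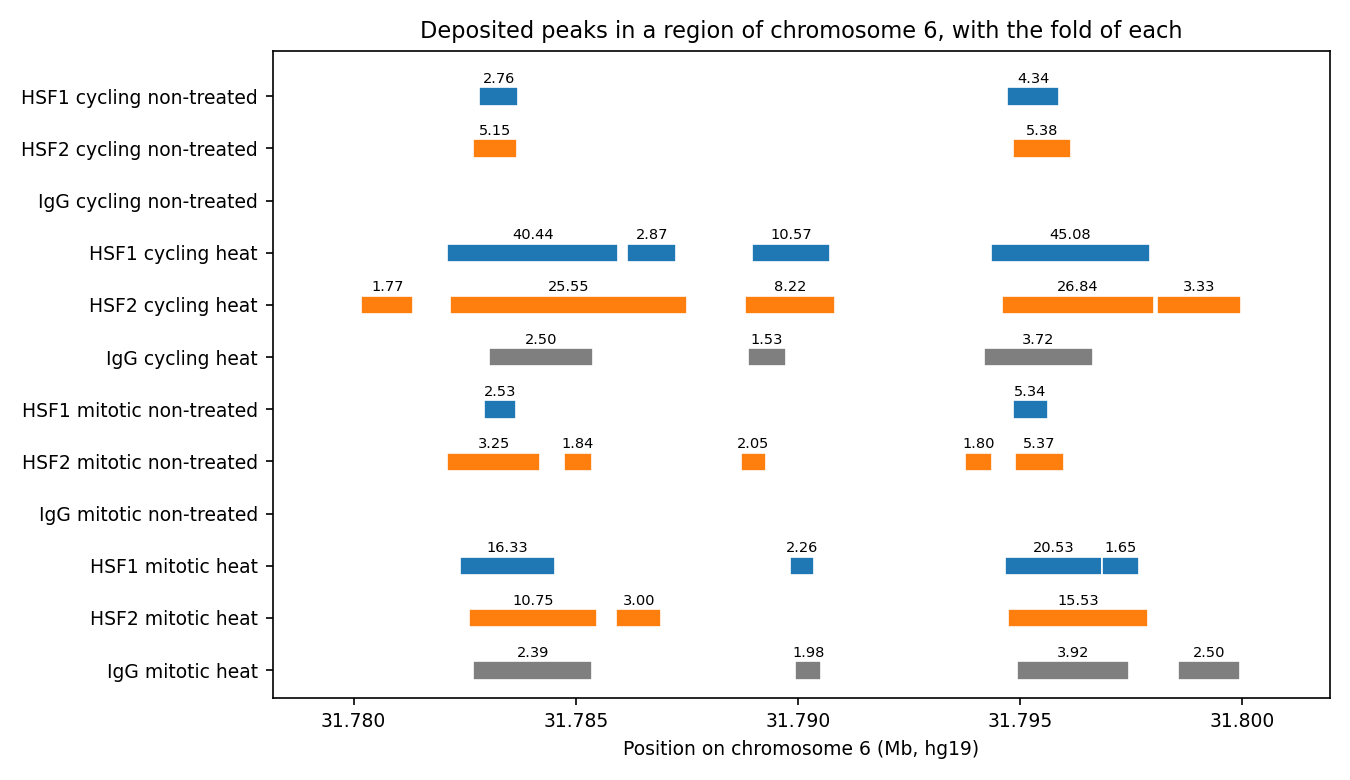
Every deposited peak around the chromosome 6 pair (horizontal axis, hg19 position) in the 12 lists (vertical axis, 1 line per list), drawn to scale with its fold above it and coloured by antibody. After heat, HSF1 folds at the pair are 40.4 and 45.1 in cycling and 16.3 and 20.5 in mitotic cells. Scaled for depth they are 84.1 and 93.8 in cycling and 84.8 and 106.6 in mitotic cells. By CPM, in peaks of unlike width, the pair has 32.1 and 35.9 in cycling and 17.1 and 22.2 in mitotic cells. The depth-scaled fold and the CPM therefore differ in direction.

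IgG peaks set the background of the unfiltered lists. IgG of the same condition overlapped 753 of the 6447 HSF1 peaks of heat-treated cycling cells (11.7%) and 12.1% of the HSF2 peaks. In heat-treated mitotic cells the shares were 49.7% for HSF1 and 36.3% for HSF2. In non-treated cells they were 20.4% for HSF1 and 39.1% for HSF2 when cycling, and 17.3% and 2.61% when mitotic. The mitotic IgG libraries differed in depth, with 2066373 kept tags and 2373 peaks without heat, and 17981369 kept tags and 41184 peaks with heat.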

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

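All tests in this part were chosen only after the results were seen.

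The number of HSF2 peaks moved in opposite directions with heat in the 2 cell states. In cycling cells the heat-treated list held 3440 more deposited HSF2 peaks than the non-treated list, and in mitotic cells the difference was -11596. The difference between the states was not tested, since each group has 1 library. HSF2 peaks with a fold of at least 5, which is not corrected for depth, went from 157 to 909 in cycling and from 54 to 613 in mitotic cells (mitotic IgG from 1 to 555). At a depth-scaled fold of at least 10, HSF2 peaks went from 12 to 668 in cycling and from 1060 to 41 in mitotic cells. IgG peaks at that scaled fold went the other way, from 383 to 62 in cycling and from 569 to 1066 in mitotic cells. Library depth stays open: the shallower HSF2 library had more peaks in both states (the mitotic heat library was 1.91 times as deep as its non-treated one and the cycling heat library 0.679 times), while in the HSF1 pairs and the mitotic IgG pair the deeper library did, 3 of the 5 pairs of the same route and input. A candidate explanation is background that IgG also gives: 28.1% of the non-treated mitotic HSF2 peaks overlapped heat-treated mitotic IgG and 10.7% overlapped heat-treated mitotic HSF2, but relative to random placement the IgG overlap was 0.695 of the HSF2 overlap. Depth, background of this kind and a difference between the states cannot be told apart by these values, and a biological difference stays untested.

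The number of IgG peaks also moved in opposite directions, with a heat-treated minus non-treated difference of -11381 in cycling and 38811 in mitotic cells. This difference was not tested either. The mitotic libraries had 2066373 kept tags without and 17981369 with heat, and the cycling lists differ in processing route and input (36542527 and 34815679 kept input tags).

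HSF1 had fewer target sites than HSF2 in heat-treated mitotic cells by fold (6 and 8) and more by depth-scaled fold (77 and 2). The deposited fold is not corrected for depth: fold per tag at shared regions hardly changed with depth over 14 pairs of mitotic lists (slope -0.0385), where a corrected fold would give -1. Lifted background alone is argued against for the scaled HSF1 peaks, since 79 of 81 (97.5%, 91.4 to 99.3) lay in the HSF1 list of heat-treated cycling cells, against 13 of 187 (6.95%, 4.11 to 11.5) for the shallowest IgG library, although 55 of the 81 had no heat-treated mitotic IgG peak and the others did. HSF1 also had more sites at a fold of 15 (difference 1) or 20 (1) and by score (2168), and HSF2 had more at a fold of 5 (547 against 34) or with no minimum (5272 against 2504), so the order depends on the definition. The score was not tested against depth. The uncorrected fold could account for the lower HSF1 count at a fold of 10, and a biological difference stays untested with 1 library each.

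Of the heat-treated cycling sites, part had a heat-treated mitotic peak. Lower depth cannot be the reason for HSF2, whose mitotic library was 1.45 times as deep as the cycling one. Other effects of depth are not excluded for HSF2, since its shallower library had more peaks in both pairs of heat-treated and non-treated lists. Its median ratio of depth-scaled fold, mitotic over cycling, was 0.244 at 56 sites without a mitotic IgG peak. These sites were selected in the cycling list, which lowers the ratio, and sites selected in the mitotic HSF2 list were not examined. For HSF1 the median ratio was 0.563 at 157 sites selected in the cycling HSF1 list, 0.588 at 95 selected in the cycling HSF2 list and 0.778 at 79 selected in the mitotic HSF1 list. At the 79 sites, 69.6% of the ratios of depth-scaled fold (58.8 to 78.7) lay below 1, which argues against lower depth alone. An earlier form of this test, on the upper quartile (1.13), had left it open. By tags, 74.7% of ratios (64.1 to 83.0) lay below 1. Tags are counted in each library's own peak, and their ratio followed that of peak widths over all shared HSF1 sites (r = 0.706). Peak width may itself change with depth, so the share by tags cannot count against depth. Interphase cells as the sole source could hold if all sites kept 1 ratio. At sites without such an IgG peak, the SD of the log2 ratio of fold was reduced by the counting error of tags in whole peaks. The result was 0.389 (0.238 to 0.493) for HSF1 and 0.304 (0.133 to 0.408) for HSF2, against 0.339 (0.287 to 0.388) for HSF2 over HSF1 within cycling cells. The fold is taken at the summit, and its own counting error was not estimated. These values therefore cannot decide, and this source cannot be told apart. The form on fold replaced earlier ones on tags. Over all shared sites the spread in tags had argued against the source, with 0.494 (0.368 to 0.601) for HSF1 and 0.803 (0.540 to 1.03) for HSF2 against 0.293 (0.240 to 0.333). At sites without such an IgG peak it was 0.491 (0.332 to 0.608) and 0.562 (0.406 to 0.688) against 0.290 (0.236 to 0.336). There it had argued against the source for HSF2 alone, since the HSF1 interval overlapped that of the comparison. At these sites the spread in tags followed the ratio of peak widths (r = 0.709 and 0.831 across sites), so the outcome depends on the measure. The processing route is open as well, since 0 of the 6 mitotic lists came by the route of the heat-treated cycling lists, and a biological difference between the states stays untested.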

How the results depend on the processing

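The tests at a depth-scaled fold, without sites that have a heat-treated mitotic IgG peak, and on the shares with a peak in another list were chosen only after the result was seen; the other alternatives were planned. Over 335 alternatives of the main counts, shared sites and shares, 175 stayed within 1.5 times the main count or inside the interval of the main share, and 160 did not. Summits within 250 bp in place of overlap left all 17 values inside. Among differences in the number of sites between lists, 50 stayed within bounds, 62 moved without a change of sign and 20 reversed. For the fold minimum, the score and the IgG removal, lists became longer or shorter by construction, and for the other alternatives the cause was not tested. The fold minimum and the score apply to HSF and IgG peaks alike, so that with no minimum every HSF peak with a matched IgG peak is removed. Whether the score changes with depth was not tested. Alternatives for heat shock elements and promoters were not run, and a setting that left a list empty gave no share and no list of equal length. The shallow mitotic HSF1 libraries and the shallow non-treated mitotic IgG library limit what a missing peak can show. They also limit what a present peak can show. The deposited fold, which is not adjusted for depth, was below 1 in 89.9% of the non-treated mitotic IgG peaks. For mitotic HSF1 it was below 1 in 48.5% of peaks without heat and 29.9% with heat. In every other list the share was at most 0.127%.

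With no fold minimum, the lists held 3754 HSF1 and 533 HSF2 sites in non-treated cycling cells, 5694 HSF1 and 3793 HSF2 sites in heat-treated cycling cells, 3751 HSF1 and 19348 HSF2 sites in non-treated mitotic cells and 2504 HSF1 and 5272 HSF2 sites in heat-treated mitotic cells. Without a minimum, HSF1 sites of heat-treated cells with a non-treated partner numbered 185 in cycling cells and 236 in mitotic cells and HSF2 sites of heat-treated cells with a non-treated partner numbered 59 in cycling cells and 435 in mitotic cells. Without a minimum, HSF1 sites of cycling cells with a mitotic partner numbered 242 without heat and 345 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 115 without heat and 203 with heat. Without a minimum, HSF1 sites with an HSF2 partner numbered 94 in non-treated cycling cells, 1728 in heat-treated cycling cells, 1181 in non-treated mitotic cells and 186 in heat-treated mitotic cells. Without a minimum, HSF1 sites of heat-treated cycling cells had a peak at 30.5% in the HSF2 list and 10.4% in the mitotic list. Without a minimum, HSF2 sites of heat-treated cycling cells had a peak at 2.56% in the non-treated list, 45.7% in the HSF1 list and 10.3% in the mitotic list.

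At a fold of 5 or more, the lists held 45 HSF1 and 149 HSF2 sites in non-treated cycling cells, 1241 HSF1 and 899 HSF2 sites in heat-treated cycling cells, 2 HSF1 and 53 HSF2 sites in non-treated mitotic cells and 34 HSF1 and 547 HSF2 sites in heat-treated mitotic cells. At fold 5, HSF1 sites of heat-treated cells with a non-treated partner numbered 4 in cycling cells and 1 in mitotic cells and HSF2 sites of heat-treated cells with a non-treated partner numbered 38 in cycling cells and 12 in mitotic cells. At fold 5, HSF1 sites of cycling cells with a mitotic partner numbered 34 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 10 without heat and 66 with heat. At fold 5, HSF1 sites with an HSF2 partner numbered 2 in non-treated cycling cells, 670 in heat-treated cycling cells, 2 in non-treated mitotic cells and 21 in heat-treated mitotic cells. At fold 5, HSF1 sites of heat-treated cycling cells had a peak at 78.5% in the HSF2 list and 23.9% in the mitotic list. At fold 5, HSF2 sites of heat-treated cycling cells had a peak at 5.9% in the non-treated list, 90.7% in the HSF1 list and 21% in the mitotic list.

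At a fold of 15 or more, the lists held 0 HSF1 sites in non-treated cycling cells, 96 HSF1 and 48 HSF2 sites in heat-treated cycling cells, 1 HSF2 site in non-treated mitotic cells and 3 HSF1 and 2 HSF2 sites in heat-treated mitotic cells. At fold 15, HSF2 sites of heat-treated cells with a non-treated partner numbered 0 in mitotic cells. At fold 15, HSF1 sites of cycling cells with a mitotic partner numbered 3 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 1 with heat. At fold 15, HSF1 sites with an HSF2 partner numbered 40 in heat-treated cycling cells and 1 in heat-treated mitotic cells. At fold 15, HSF1 sites of heat-treated cycling cells had a peak at 12.5% in the non-treated list and 81.2% in the mitotic list. At fold 15, HSF2 sites of heat-treated cycling cells had a peak at 35.4% in the non-treated list, 100% in the HSF1 list and 83.3% in the mitotic list.

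At a fold of 20 or more, the lists held 0 HSF1 and 1 HSF2 sites in non-treated cycling cells, 40 HSF1 and 18 HSF2 sites in heat-treated cycling cells, 0 HSF2 sites in non-treated mitotic cells and 1 HSF1 and 0 HSF2 sites in heat-treated mitotic cells. At fold 20, HSF2 sites of heat-treated cells with a non-treated partner numbered 1 in cycling cells. At fold 20, HSF1 sites of cycling cells with a mitotic partner numbered 1 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 0 with heat. At fold 20, HSF1 sites with an HSF2 partner numbered 16 in heat-treated cycling cells and 0 in heat-treated mitotic cells. At fold 20, HSF1 sites of heat-treated cycling cells had a peak at 25% in the non-treated list, 95% in the HSF2 list and 92.5% in the mitotic list. At fold 20, HSF2 sites of heat-treated cycling cells had a peak at 61.1% in the non-treated list, 100% in the HSF1 list and 94.4% in the mitotic list.

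With a score of 100 in place of the fold, the lists held 738 HSF1 and 49 HSF2 sites in non-treated cycling cells, 2256 HSF1 and 1204 HSF2 sites in heat-treated cycling cells, 2832 HSF1 and 8440 HSF2 sites in non-treated mitotic cells and 2476 HSF1 and 308 HSF2 sites in heat-treated mitotic cells. By score, HSF1 sites of heat-treated cells with a non-treated partner numbered 59 in cycling cells and 156 in mitotic cells and HSF2 sites of heat-treated cells with a non-treated partner numbered 12 in cycling cells and 59 in mitotic cells. By score, HSF1 sites of cycling cells with a mitotic partner numbered 104 without heat and 331 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 18 without heat and 40 with heat. By score, HSF1 sites with an HSF2 partner numbered 21 in non-treated cycling cells, 940 in heat-treated cycling cells, 653 in non-treated mitotic cells and 73 in heat-treated mitotic cells. By score, HSF1 sites of heat-treated cycling cells had a peak at 61% in the HSF2 list and 20.1% in the mitotic list. By score, HSF2 sites of heat-treated cycling cells had a peak at 4.65% in the non-treated list, 87.7% in the HSF1 list and 19.9% in the mitotic list.

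With an FDR of at most 5% added, the lists held 0 HSF2 sites in non-treated cycling cells. With the FDR, HSF2 sites of heat-treated cells with a non-treated partner numbered 0 in cycling cells.

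Without removal of IgG peaks, HSF2 sites of heat-treated cells with a non-treated partner numbered 3 in mitotic cells.

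After removal of every matched IgG peak, the lists held 1 HSF2 site in non-treated mitotic cells and 2 HSF1 and 3 HSF2 sites in heat-treated mitotic cells. After that removal, HSF2 sites of heat-treated cells with a non-treated partner numbered 0 in mitotic cells. After that removal, HSF1 sites of cycling cells with a mitotic partner numbered 2 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 2 with heat. After that removal, HSF1 sites with an HSF2 partner numbered 0 in heat-treated mitotic cells.

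After removal of strong peaks of all 4 IgG lists, the lists held 1 HSF2 site in non-treated mitotic cells.

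After removal of every peak of all 4 IgG lists, the lists held 0 HSF1 sites in non-treated cycling cells, 0 HSF2 sites in non-treated mitotic cells and 2 HSF1 and 3 HSF2 sites in heat-treated mitotic cells. With all IgG peaks removed, HSF2 sites of heat-treated cells with a non-treated partner numbered 0 in mitotic cells. With all IgG peaks removed, HSF1 sites of cycling cells with a mitotic partner numbered 2 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 2 with heat. With all IgG peaks removed, HSF1 sites with an HSF2 partner numbered 0 in heat-treated mitotic cells. With all IgG peaks removed, HSF1 sites of heat-treated cycling cells had a peak at 3.11% in the non-treated list. With all IgG peaks removed, HSF2 sites of heat-treated cycling cells had a peak at 100% in the HSF1 list.

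With 50% reciprocal overlap, HSF1 sites of heat-treated cycling cells had a peak at 2.81% in the non-treated list and 49.1% in the mitotic list.

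Looked for among all deposited peaks, HSF1 sites of heat-treated cells with a non-treated partner numbered 16 in cycling cells and 3 in mitotic cells and HSF2 sites of heat-treated cells with a non-treated partner numbered 29 in cycling cells and 6 in mitotic cells. Among deposited peaks, HSF1 sites of cycling cells with a mitotic partner numbered 157 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 5 without heat and 81 with heat. Among deposited peaks, HSF1 sites with an HSF2 partner numbered 280 in heat-treated cycling cells and 6 in heat-treated mitotic cells.

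In lists of equal length, HSF2 sites of heat-treated cells with a non-treated partner numbered 1 in cycling cells and 2 in mitotic cells. At equal length, HSF1 sites with an HSF2 partner numbered 1 in heat-treated mitotic cells.

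At a depth-scaled fold of 20 or more, the lists held 3 HSF1 and 3 HSF2 sites in non-treated cycling cells, 6 HSF1 sites in non-treated mitotic cells and 77 HSF1 and 2 HSF2 sites in heat-treated mitotic cells. At that scaled fold, HSF1 sites of heat-treated cells with a non-treated partner numbered 2 in mitotic cells and HSF2 sites of heat-treated cells with a non-treated partner numbered 0 in mitotic cells. At that scaled fold, HSF1 sites of cycling cells with a mitotic partner numbered 66 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 1 without heat and 1 with heat. At that scaled fold, HSF1 sites with an HSF2 partner numbered 3 in non-treated mitotic cells and 1 in heat-treated mitotic cells. At that scaled fold, HSF2 sites of heat-treated cycling cells had a peak at 63.5% in the mitotic list.

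Without the sites that had a heat-treated mitotic IgG peak, HSF1 sites of cycling cells with a mitotic partner numbered 2 with heat and HSF2 sites of cycling cells with a mitotic partner numbered 2 with heat. Without these sites, HSF1 sites of heat-treated cycling cells had a peak at 3.48% in the non-treated list. Without these sites, HSF2 sites of heat-treated cycling cells had a peak at 100% in the HSF1 list.

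With no fold minimum, the differences with a reversed sign were -1247 for HSF1 in mitotic cells (heat-treated minus non-treated), -14076 for HSF2 in mitotic cells (heat-treated minus non-treated), -18815 for HSF2 without heat (cycling minus mitotic), -1479 for HSF2 with heat (cycling minus mitotic) and 3221 in non-treated cycling cells (HSF1 minus HSF2). The difference of -1247 comes from an unequal IgG removal. Matched IgG overlapped 49.7% of the heat-treated and 17.3% of the non-treated mitotic HSF1 peaks. Before removal these lists held 4982 and 4534 peaks. With a score of 100 in place of the fold, the differences with a reversed sign were -356 for HSF1 in mitotic cells (heat-treated minus non-treated), -8132 for HSF2 in mitotic cells (heat-treated minus non-treated), -2094 for HSF1 without heat (cycling minus mitotic), -220 for HSF1 with heat (cycling minus mitotic), -8391 for HSF2 without heat (cycling minus mitotic), 689 in non-treated cycling cells (HSF1 minus HSF2) and 2168 in heat-treated mitotic cells (HSF1 minus HSF2). At a depth-scaled fold of 20 or more, the differences with a reversed sign were -4 for HSF2 in mitotic cells (heat-treated minus non-treated), -3 for HSF1 without heat (cycling minus mitotic), -3 for HSF2 without heat (cycling minus mitotic) and 75 in heat-treated mitotic cells (HSF1 minus HSF2). With an FDR of at most 5% added, the differences with a reversed sign were -4 for HSF2 without heat (cycling minus mitotic) and 1 in non-treated cycling cells (HSF1 minus HSF2). At a fold of 15 or more, the difference with a reversed sign was 1 in heat-treated mitotic cells (HSF1 minus HSF2). At a fold of 20 or more, the difference with a reversed sign was 1 in heat-treated mitotic cells (HSF1 minus HSF2).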

Other observations

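No explanation is weighed in this part, and its tests on chromosomes were chosen only after the result was seen.

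HSF1 sites of heat-treated cycling cells were unevenly spread over the chromosomes. Chromosome 19 held 32 of the 285 sites (11.2%, 8.07 to 15.4), against 1.91% of the covered span and 3.86% of the IgG peaks of the same cells (adjusted p = 9.50e-14 against span, exact binomial test, and 8.03e-06 against IgG, Fisher's exact test). Chromosome 11 held 26 (9.12%, adjusted p = 0.00491 and 8.03e-06 by the same exact tests) and chromosome 17 held 18 (6.32%, adjusted p = 0.00603 and 0.0238). Chromosome 4 held 2 (0.702%), against 6.17% of the span (adjusted p = 8.97e-05) and 3.75% of the IgG peaks (adjusted p = 0.0253, the same exact tests). HSF2 gave 18 of its 156 sites on chromosome 19 (11.5%, adjusted p = 3.78e-08 and 0.000835, exact tests). Gene density was not analysed here.

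Several HSF1 sites had a neighbour within 20 kb. Heat-treated cycling cells had 15 such pairs for HSF1 and 4 for HSF2. On chromosome 6 the HSF1 summits at 31783167 and 31795325 had a weaker site between them at 31790022 (fold 10.6). On chromosome 7 summits at 75924125 (fold 39.5) and 75931832 (fold 23.8) lay 7707 bp apart, and HSF2 had the same pair 7681 bp apart. On chromosome 19 summits at 2678353 and 2679642 lay 1289 bp apart for HSF1, with folds of 15 and 27.7, and 1296 bp apart for HSF2. On chromosome 16 summits at 89039995 and 89050702 lay 10707 bp apart. These pairs were chosen after their values were seen.

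Over all 12 lists, 73247 of 86567 merged regions (84.6%) had a peak in 1 list, and 62 had one in all 12.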
